A study of Homo sapiens with 21 samples.

How the data were processed

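The data were ATAC-seq peak lists of 21 libraries from microglia-like cells of 7 isogenic H9 lines, 3 libraries per line. Per the labels' protocols, H9 cells were edited with CRISPR/Cas9, taken through haematopoietic progenitors and 28 days of microglial differentiation, sorted (80000 cells) and processed by Omni-ATAC, with paired-end sequencing on a NextSeq. Per the submitters' processing notes the tools were cutadapt 1.18, STAR 2.7, HOMER 4.10 and DESeq2; what DESeq2 was used for is not given in the sources used here. Per the file headers, peaks were called by HOMER findPeaks in histone style, library by library and without a control library, with a peak size of 500, a minimum distance between peaks of 1000, at least 4.00 times the tags of the surrounding 10000 bp, and a Poisson p of 1.00e-04 over the local region. The score column, as deposited, holds 1 for every peak, so the lists give positions and no height. Tags per library, per the file headers, are given in units of M (1 M being 1000 times 1000). Whether reads were shifted for the transposase cut is not given in the sources used here.

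The genome build is not given in the sources used here. Gene names and neighbours came from a RefSeq gene table of GRCh38.p14 with 19970 genes, and region coordinates are those of the deposited lists, counted from 1. Of 39940 gene ends, 21.9% lay under a region called in all 21 libraries, and 2.75% and 2.86% when the ends were shifted by 10 kb either way. The table has no strand, so a gene end means a region within 1 kb of either end of a gene, and a region was assigned to the nearest gene span within 100 kb (78.7% of regions). Of 584 genes in the fixed lists 2 had no match. Peaks on chromosomes Y and M, 0.082% of 1604926, were left out of all comparisons.

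Peaks sharing at least 1 bp were merged over all libraries into 166736 regions, and a library called a region if any of its peaks lay in it. To reduce the effect of depth, the depth-adjusted call is the call minus the mean call, in the same library, of all regions called in the same number of libraries. It was averaged per gene (at least 5 regions, 8424 genes), per gene list (23 lists) and per chromosome (23), and tested with limma over all 21 libraries with Benjamini-Hochberg adjustment, per comparison for genes and over 138 tests for lists and chromosomes against WT. The comparisons of 2 alleles of the same gene had a family of 46 tests, which was chosen after the unadjusted p had been seen. Similarity of peak sets was the Jaccard index in bp with 100000 permutations of the line labels, two-sided. All-or-none regions were called in 3 of 3 libraries of a line and 0 of 3 of the other, with no test per region, and were set beside 100 simulations in which each library's chance of calling a region followed only its depth and the region's recurrence. Line-specific regions were set beside 100 draws of 3 libraries.

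The groups, tests, gene lists and most alternatives were fixed before the data were examined. Deviations followed from the files. Without a varying score, settings that rank peaks by score were replaced by settings that use the order of peaks in each list. That order carries strength to some degree: the first part of each list, 10% of its peaks, was called in 19.9 to 20.0 of the other libraries and the last in 4.16 to 13.8, with a fall at every step in 19 of 21 libraries. Gene spans and gene ends replaced transcription start sites and promoters. Motifs were not tested, as no genome sequence was used here.

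Named regions were, per comparison, up to 10 gained and 10 lost regions that stayed all-or-none with lists of equal length and stood highest in the file order, gene ends first. Named genes were APOE and the 4 edited genes, up to 10 genes past the threshold in each direction, and up to 4 members of a list that passed. Alternatives were a cover of at least 50% of a region, regions called in at least 2 libraries, leaving out each replicate number or the SORL1-A528T libraries, at least 10 regions per gene, gene-end regions alone, camera and fry, and the replicate number as a block. Equal list lengths (39711 peaks), the upper part of each list and an expectation matched on gene density were chosen after seeing the data.

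The tests were tried on simulated data for TREM2-R47H against WT. Of genes given an added call rate of 0.3 and 0.5, 19.2% and 42.0% of 99 and 100 were found. Smaller differences per gene were thus often below what 3 libraries can show. Call rates were capped at 1, so regions that most libraries call gained less than the added rate. Of the 7739 other genes 5 were called. The 7739 include genes of the changed lists and on chromosomes that were also changed, so the 5 need not be false calls. Of the lists, 2 of 3 were found at 0.1 and 3 of 3 at 0.2. Of the 17 other lists, which can hold genes of the changed lists or chromosomes, 0 were called. Simulated calls were drawn independently for each region and library, without shifts shared by many regions of a library. The real libraries show such shifts, so these rates need not hold for the real data. The tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.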

Results

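Open chromatin was profiled by ATAC-seq, in which a transposase cuts and tags accessible DNA, in microglia-like cells grown from H9, an established human embryonic stem cell line. The 21 libraries came from 7 lines with 3 libraries each. Besides unedited WT, TREM2 (a lipid-sensing receptor of microglia) was altered in the TREM2-R47H and TREM2-KO lines, and SORL1 (an endosomal sorting receptor) in the SORL1-A528T and SORL1-KO lines. The CD33 SNP and INPP5D SNP lines carried an edited single-nucleotide variant at the gene of an inhibitory sialic acid receptor and of an inositol phosphatase. The libraries titled SORL1-A528T were grouped by title, although their genotype label names TREM2-KO, so each statement on SORL1-A528T concerns the libraries so titled. Nothing in the labels says whether replicates came from separate differentiations, so p-values measure the spread between these libraries, which may be technical.

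The peak lists held 39736 to 102891 peaks per library and merged into 166736 regions with a median width of 737 bp. Of these regions, 25599 (15.4%) were called in all 21 libraries and 42992 (25.8%) in 1 library. Gene ends, meaning positions within 1 kb of either end of an annotated gene, held 29.7% of the regions called in every library and 2.8% of those called in 1. Depth followed the replicate number and not the line: replicate 1 had 56.5 to 67.4 M tags, replicate 2 had 12.8 to 17.5 M and replicate 3 had 32.6 to 52.9 M. Peak number did not differ detectably between lines (F = 0.334, permutation p = 0.912). With the replicate number as a block, F was 2.76 (permutation p = 0.0948). WT had 79549 ± 28201 peaks (SD, n = 3) and the lowest mean was 62635 ± 20304 (SD, n = 3) in SORL1-A528T. The SORL1-A528T list was the shortest of each replicate number (69732, 39736 and 78438 peaks). Against WT, each edited line gave an exact permutation p between 0.5 and 1.0, where 3 against 3 libraries cannot go below 0.1.

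**Figure D1:**
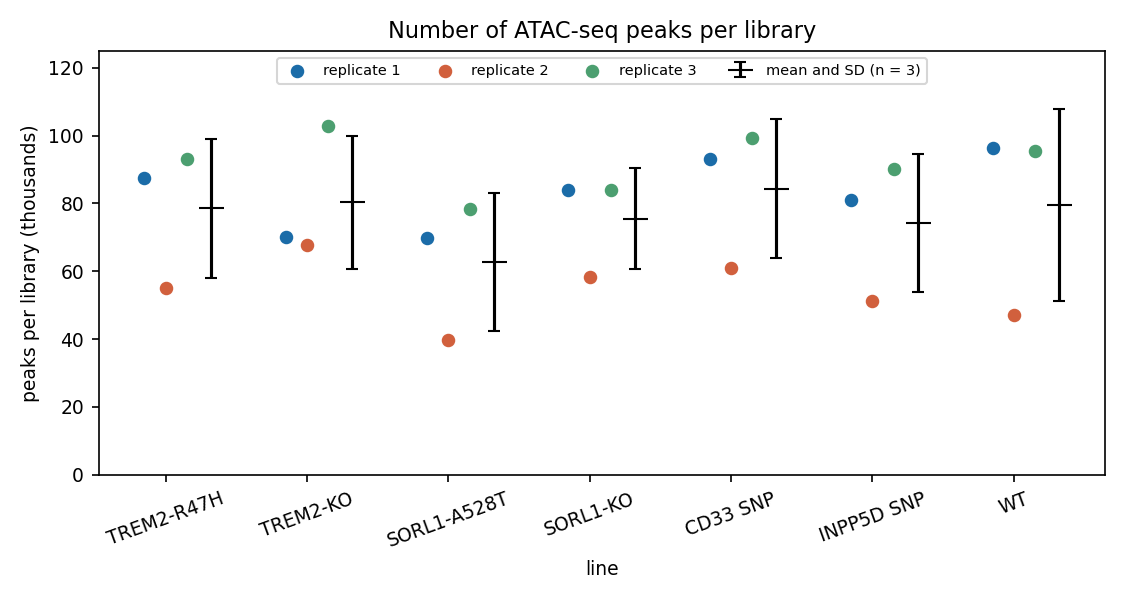
Number of called peaks per library (vertical axis, in units of 1000 peaks) for each of the 7 lines, with points coloured by replicate number and the mean ± SD (n = 3) beside them. Replicate 2 lists, from 12.8 to 17.5 M tags, are the shortest of each line, and the SORL1-A528T mean of 62635 is the lowest.

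Libraries resembled each other more by replicate number than by line. The shared share of covered base pairs (Jaccard index) was 0.513 ± 0.0879 (SD, 21 pairs) within lines and 0.534 ± 0.0898 between lines, a difference of -0.0206 (permutation p = 0.132, two-sided). Pairs from different lines with the same replicate number shared 0.594 ± 0.0620, above pairs from different lines with other numbers at 0.504 ± 0.0866. Pairs of the same line always have other numbers, so their 0.513 is better set beside this 0.504, which turns the direction of the difference. With permutations held within replicate numbers their mean was -0.0295, so libraries of a line were more alike than in those permutations (permutation p = 0.00064). The numbers were not taken to pair the libraries. Without the shallow replicate 2 libraries the difference between lines was 0.00186 (permutation p = 0.867), and without replicate 3 it was -0.0627 (permutation p = 0.0428).

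Chromatin around APOE, the lipid-carrier gene that the series title names as a point of convergence, was called most often in TREM2-R47H. Of the calls possible over 5 regions within 10 kb of APOE (chromosome 19, 44903424 to 44915751), TREM2-R47H held 12 (80.0%), SORL1-KO 9 (60.0%), INPP5D SNP 8 (53.3%), CD33 SNP and WT 6 each (40.0%), and TREM2-KO and SORL1-A528T 4 each (26.7%). A region between APOE and APOC1, outside both gene spans (19, 44910768 to 44911690), was called in 3 of 3 TREM2-R47H libraries, in 2 of 3 in SORL1-KO, CD33 SNP and INPP5D SNP, in 1 of 3 in WT and in 0 of 3 in TREM2-KO and SORL1-A528T. The region over the APOE gene end (19, 44905297 to 44906959) was called in 10 libraries, none of them a shallow replicate 2 library, and the APOC1 gene end (19, 44914156 to 44915751) in all 21. These calls were given as values with no test and no adjustment for depth, and the SORL1-A528T lists were the shortest of each replicate number.

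**Figure D2:**
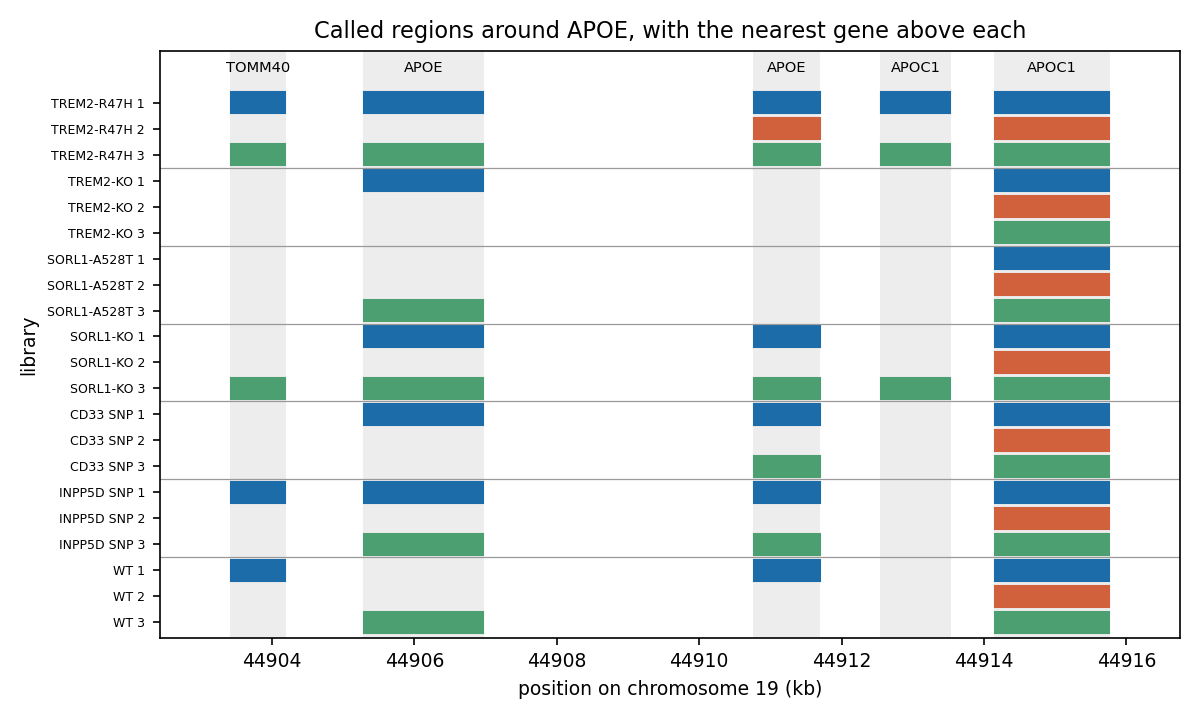
Called regions around APOE on chromosome 19 (position in kb, horizontal axis) in each of the 21 libraries (vertical axis), with grey bands for the 5 regions, the nearest gene above each band and blocks coloured by replicate number. TREM2-R47H fills 12 of its possible calls and TREM2-KO 4, while the APOC1 gene end is called in all 21 libraries.

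The gene ends of TREM2 and SORL1 were called in the knockout lines. The TREM2 gene end (6, 41161604 to 41163617) was called in 19 of 21 libraries, including 3 of 3 TREM2-KO libraries, and the SORL1 gene end (11, 121451552 to 121453044) in 19, including 3 of 3 SORL1-KO and 2 of 3 SORL1-A528T libraries. Across 21 regions at SORL1, 60.3% of possible calls were made in SORL1-KO, 63.5% in WT and 44.4% in SORL1-A528T. Such shares are not adjusted for depth, and the SORL1-A528T list was the shortest of each replicate number. At CD33 the CD33 SNP line held 86.7% of possible calls and WT 73.3%, and at INPP5D the INPP5D SNP line held 65.2% and WT 68.2%. A peak call does not test whether an edit removed the protein, so these values check no label. In the gene test over 8 comparisons the difference ranged from -0.0516 to 0.0425 for SORL1, from -0.0459 to 0.0279 for INPP5D and from -0.0970 to 0.203 for CD33, with no adjusted p (limma) below 0.302; APOE and TREM2 had fewer than the 5 regions the test required.

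TREM2-R47H against WT compared a TREM2 variant known as a risk factor for Alzheimer's disease with the unedited line. TREM2-R47H lacked the gene-end region of PUS7L, a gene of the pseudouridine synthase family (12, 43757989 to 43759848), which stood at a median percentile of 93.8 in the file order of the WT lists (100 being the first peak) and was called in every library of the other lines. Also called in 3 of 3 WT and 0 of 3 TREM2-R47H libraries were the gene end of H2BC3, a histone H2B gene (6, 26043086 to 26046050), and regions at GRIN3A, an NMDA receptor subunit (9, 101572659 to 101573713), at DKK2, a secreted Wnt antagonist (4, 106903756 to 106905391), and inside PDZRN3 (3, 73413137 to 73414004), PKD1L1 (7, 47937155 to 47938799) and TMED3 (15, 79370561 to 79372934). In the other direction, a region outside gene spans near PRDM11 (11, 45072812 to 45074316) was called in 3 of 3 TREM2-R47H and 0 of 3 WT libraries. In all, 212 regions were gained and 505 lost, against means of 108 and 136 in 100 simulations with no difference between lines. Near genes of the fixed lists, gained regions lay at FOSL2, NFKBIZ, NME8 and SLC24A4, and lost regions at SYK (a kinase downstream of TREM2), SOD2, MRC1 and COL3A1. Such list genes are examples, here and in the comparisons below. Whether all-or-none regions lay near list genes more often than other regions was not tested.

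Per gene, the mean depth-adjusted call (the call minus the rate expected for regions of the same recurrence in that library) was compared with limma over 8424 genes. Genes named below for the smallest adjusted p, from an alternative setting or as examples near all-or-none regions, and BCOR, were chosen after their values were seen. None passed in TREM2-R47H against WT after Benjamini-Hochberg adjustment (limma, 0 genes; 423 higher and 299 lower at an unadjusted p below 0.05). The smallest adjusted p (limma, 0.296) belonged to MED14, a Mediator subunit, with a difference of 0.457 (SE 0.0888; higher in 3 of 3 libraries), and BCOR, a transcriptional corepressor gene near it on the X chromosome, had 0.297 (SE 0.0702, adjusted p = 0.296 by limma). MRC1, the macrophage mannose receptor, had -0.230 (SE 0.0668), GFI1, a repressor in blood cell development, had -0.231 (SE 0.0561), and FCER1A, a mast cell receptor subunit, had -0.383 (SE 0.110). These 3 account for the 4 calls adjusted over the list alone, MRC1 being in 2 lists. FCER1A varied widely in WT, at 0.262 ± 0.316 (SD, n = 3). All 23 gene lists had a positive difference, the housekeeping, neural and pluripotent lists among them. Over the 21 libraries 22 of the 23 lists correlated negatively with the share of regions outside gene spans. That share was 43.5%, 40.6% and 43.6% in WT 1 to 3 and 41.7%, 40.5% and 42.7% in TREM2-R47H 1 to 3. After adjustment 0 lists passed (limma, with 4 at an unadjusted p below 0.05, over 138 tests). The 4 were homeostatic microglia with 0.0876 (SE 0.0375), the APOE cluster with 0.168 (SE 0.0743), Alzheimer risk loci with 0.0634 (SE 0.0288) and interferon response with 0.0596 (SE 0.0273), each with an adjusted p of 0.923 (limma) and higher in 3 of 3 libraries. The APOE cluster fell to 0.103 without TREM2-R47H 1 and interferon response to 0.0362 without WT 3. With every list limited to its first 39711 peaks, a setting chosen after seeing the data, the gained count was 441, only 1 of the 212 gained and 10 of the 505 lost regions being all-or-none in both settings, and SMS, spermine synthase, was the 1 gene that passed (0.395, SE 0.0662, adjusted p = 0.0383 by limma).

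A stretch of the X chromosome around BCOR (X, 39500001 to 40500000) was called more often in TREM2-R47H than elsewhere; it was chosen after its values were seen. Over its 53 regions the mean depth-adjusted call was 0.286 ± 0.035 (SD, n = 3) in TREM2-R47H and -0.048 in the 18 other libraries. The lowest TREM2-R47H library had 0.255 and the highest other library 0.053. Of possible calls over the 25 BCOR regions in the stretch, 88.0% were made in TREM2-R47H and 47.1% in the others.

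**Figure D3:**
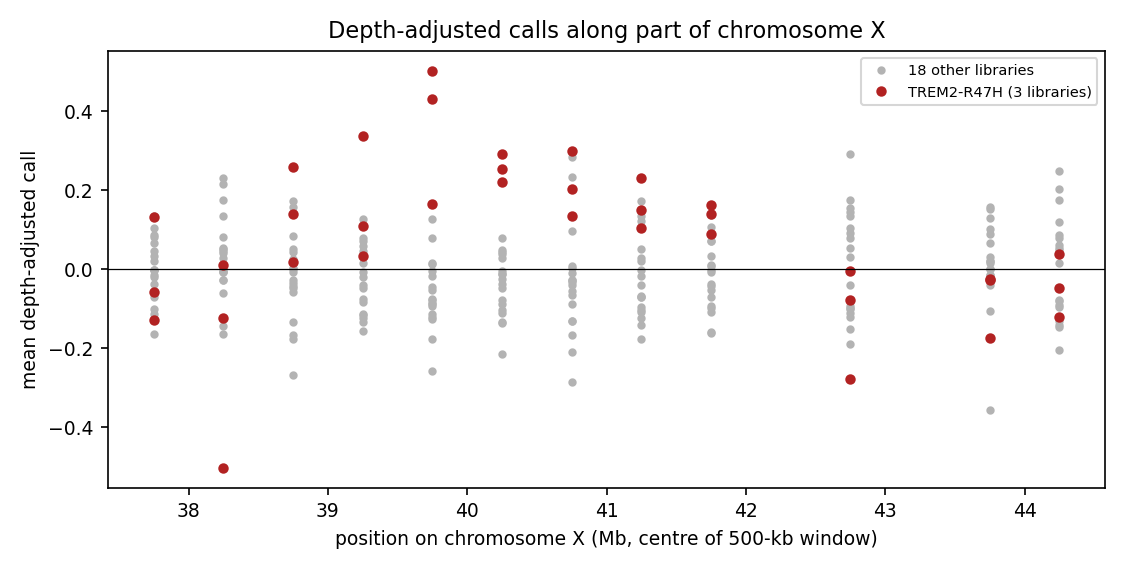
Mean depth-adjusted call (vertical axis) in windows of 500 kb along part of the X chromosome (window centre in Mb, horizontal axis), with red points for the 3 TREM2-R47H libraries and grey points for the 18 others. Over the stretch from 39500001 to 40500000 the TREM2-R47H mean is 0.286 and that of the others -0.048.

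TREM2-KO against WT differed at few sites. TREM2-KO lacked the gene-end region of CRYZ, which encodes a quinone oxidoreductase (1, 74732331 to 74734386); it stood at a median percentile of 95.3 in the WT lists and was called in every library of the other lines. The H2BC3 gene end was also called in 3 of 3 WT and 0 of 3 TREM2-KO libraries. Lost regions lay near ADAM10, the main alpha-secretase, FERMT2 and FN1, and a gained region near EGR2. The totals were 80 gained and 96 lost, below the simulated means of 171 and 181. Of these, 0 gained and 2 lost regions, the CRYZ and H2BC3 gene ends, were also all-or-none with lists of equal length. No gene passed (limma, 0 of 8424; 123 higher and 173 lower at an unadjusted p below 0.05). FCER1A had -0.423 (SE 0.110, adjusted p = 0.957 by limma) and was the 1 call adjusted over the list alone. Its WT libraries spread widely (SD 0.316, n = 3). Of the 23 lists, 19 had a negative difference and 0 passed (limma; 0 at an unadjusted p below 0.05), with TREM2-KO 2 and 3 both below TREM2-KO 1 in 21; among the 19 were disease-associated microglia with -0.0465 (SE 0.0415) and the APOE cluster with -0.0751 (SE 0.0743). When 1 TREM2-KO library was left out, they moved to between -0.0927 and -0.0166 and between -0.138 and -0.0220. With the upper part of each list alone, again chosen after seeing the data, TBL1X, a corepressor subunit gene on the X chromosome, passed (0.420, SE 0.0730, adjusted p = 0.0474 by limma).

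In SORL1-A528T against WT all-or-none regions were mostly losses, a tilt that the shorter SORL1-A528T lists also gave in simulations without a difference. The number lost was above the highest of the 100 simulations. Regions missing from 3 of 3 SORL1-A528T libraries and present in every library of the 6 other lines lay in CADM2, a synaptic adhesion gene (3, 85504050 to 85505659), in TAS2R1 (5, 9712616 to 9713684), and outside gene spans near CYLD, a deubiquitinase gene that restrains NF-kB (16, 50842016 to 50843121), WWC1 (5, 168281913 to 168282929), ODF2L (1, 86323790 to 86324817) and SUPT20HL1 (X, 24412651 to 24413756). A region near the chemokine gene CCL20 (2, 227789215 to 227790510) and regions in CPED1 and TMEM178B were lost as well, as was the H2BC3 gene end. A region inside CEP85L (6, 118573822 to 118574736) was gained. The totals were 19 gained and 812 lost, with simulated means of 21 and 616 (at most 33 and 658). With lists of equal length there were 129 and 390, mostly other regions, since 1 gained and 14 lost regions were all-or-none in both settings. No gene passed (limma, 0 of 8424; 155 higher and 187 lower at an unadjusted p below 0.05), and none did when adjusted over the list alone. ALX4 had the smallest adjusted p (-0.435, SE 0.0853, adjusted p = 0.465 by limma). Of the lists, 19 of 23 had a positive difference and 0 passed (limma; 0 at an unadjusted p below 0.05).

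SORL1-KO against WT was led by CAT, the gene of catalase, which breaks down hydrogen peroxide. Its gene-end region (11, 34438265 to 34439846) was called in all 18 libraries of the other lines, at a median percentile of 85.9 in WT, and in 0 of 3 SORL1-KO libraries. A region inside PLXDC2 (10, 19844646 to 19847109) was lost too, and regions near JUN, COL3A1 and FN1 were lost while 1 near TNFAIP3 was gained. The totals were 104 gained and 389 lost, against simulated means of 79.2 and 201; with lists of equal length 232 were gained, and 0 of the 104 gained and 2 of the 389 lost regions were all-or-none in both settings. No gene passed (limma, 0 of 8424; 233 higher and 167 lower at an unadjusted p below 0.05). OLFML3, a secreted protein of homeostatic microglia, had 0.229 (SE 0.0627, adjusted p = 0.934 by limma, higher in 3 of 3 libraries) and was the 1 call adjusted over the list alone. The APOE cluster had 0.137 (SE 0.0743) and disease-associated microglia 0.0679 (SE 0.0415), each with an adjusted p of 0.923 (limma); 21 of 23 lists were positive and 0 passed (limma; 0 at an unadjusted p below 0.05). Without replicate 1, CSK, an inhibitor of Src kinases (0.524, adjusted p = 0.0426 by limma), and TIMP2, a metalloprotease inhibitor (0.510, adjusted p = 0.0383 by limma), were higher in SORL1-KO.

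In CD33 SNP against WT the gene end of ZNF506, a zinc finger gene (19, 19821102 to 19822249), was missing from 3 of 3 CD33 SNP libraries and called in all 18 libraries of the other lines, at a median percentile of 66.7 in WT. The H2BC3 gene end was lost as in 3 other lines. Gained regions included 1 near CX3CR1, the fractalkine receptor of microglia, 1 near NLRP3, the inflammasome sensor, and 1 near ECHDC3, an Alzheimer risk locus. The totals were 159 gained and 69 lost, with simulated means of 222 and 70.1. Only the ZNF506 and H2BC3 gene ends, 0 gained and 2 lost regions, were also all-or-none with lists of equal length. No gene passed (limma, 0 of 8424; 146 higher and 68 lower at an unadjusted p below 0.05). NLRP3 had 0.204 over 17 regions (SE 0.0552, adjusted p = 0.999 by limma, higher in 3 of 3 libraries) and was the 1 call adjusted over the list alone. Of the 23 lists 18 were positive and 0 passed (limma; 0 at an unadjusted p below 0.05).

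In INPP5D SNP against WT, NAA35, a subunit of an N-terminal acetyltransferase, was lower: its mean depth-adjusted call over 5 regions fell by 0.412 (SE 0.0649, adjusted p = 0.0290 by limma), from 0.232 ± 0.0087 (SD, n = 3) in WT to -0.179 ± 0.0625 in INPP5D SNP, with 3 of 3 libraries below the WT mean. The difference in NAA35 from WT was -0.321 in TREM2-R47H, -0.293 in SORL1-KO and -0.245 in SORL1-A528T, none of which passed. NAA35 was the only gene past the threshold in the 8 comparisons (limma; here 131 genes were higher and 119 lower at an unadjusted p below 0.05). The NAA35 call was lost, at the same difference of -0.412, when peaks had to cover 50% of a region (SE 0.0739, adjusted p = 0.150 by limma) and when any of the 3 replicate numbers was left out, where the difference stayed between -0.457 and -0.387 with fewer libraries. With lists of equal length and with the upper part of each list NAA35 had too few regions to enter, and 0 genes passed (limma), so those settings neither keep nor end the call. A region inside BRI3BP (12, 125049200 to 125050166) was lost, as were regions near COL3A1 and the interferon-induced MX2, and a region near SLC24A4, an Alzheimer risk locus, was gained. The totals were 46 gained and 237 lost, with simulated means of 56.6 and 216. There were 114 and 109 with lists of equal length, of which 0 and 2 were all-or-none in both settings. Adjusted over the list alone, FCER1A (-0.356, SE 0.110, with a wide WT SD of 0.316) was the 1 call. Of the 23 lists 18 were positive and 0 passed (limma, with 0 at an unadjusted p below 0.05).

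TREM2-R47H against TREM2-KO compared the risk variant with loss of the same gene. For the APOE cluster and for disease-associated microglia genes it had the largest difference of the 8 comparisons, within a shift that ran through 22 of 23 lists. The APOE cluster, the genes next to APOE on chromosome 19, had a mean depth-adjusted call of 0.113 ± 0.118 (SD, n = 3) in TREM2-R47H and -0.130 ± 0.117 in TREM2-KO, a difference of 0.243 (SE 0.0743). Disease-associated microglia genes, the programme microglia take up around plaques, had 0.0599 ± 0.0469 and -0.0722 ± 0.0812, a difference of 0.132 (SE 0.0415), and 16 of its 16 tested genes were positive, among them the lysosomal protease CTSD (0.373, SE 0.107). Lists with a positive difference numbered 22 of 23, and 10 had an unadjusted p below 0.05 while 0 passed adjustment over 46 tests (limma; the adjusted p was 0.118 for both lists named, each higher in 3 of 3 libraries). Besides these, the 10 were immediate early genes (0.0928, SE 0.0340), Alzheimer risk loci (0.0748, SE 0.0288), interferon response (0.0689), antigen presentation (0.145), cholesterol and lipid handling (0.0693), homeostatic microglia (0.0808), and the off-lineage lists of mast cells and granulocytes (0.0643) and of mesenchyme and endothelium (0.0480). Leaving out 1 library moved 3 of these by over 1.5 times: cholesterol and lipid handling to 0.0457 without TREM2-R47H 1 and 0.0452 without TREM2-KO 2, mesenchyme and endothelium to 0.0304 without TREM2-R47H 1, and mast cells and granulocytes to 0.100 without TREM2-KO 1. With the expectation matched on gene density as well, which was chosen after seeing the data, the APOE cluster (0.153, SE 0.0364) and disease-associated microglia (0.0759, SE 0.0185) passed (adjusted p = 0.00996 for each by limma). Without replicate 1, 5 lists passed, both of these among them (adjusted p of 0.00677 and 0.00654 by limma). With the replicate number as a block, which was not taken to pair the libraries, 8 lists passed (limma). Without replicate 2, without replicate 3 and with lists of equal length 0 passed (limma; 5, 2 and 4 at an unadjusted p below 0.05). The differences rest largely on 2 libraries: TREM2-KO 2 and TREM2-KO 3 had 45.8% and 45.6% of their regions outside gene spans, where the other 19 libraries had at most 43.9% and TREM2-KO 1 had 40.4%, and both lay below TREM2-KO 1 in 21 of 23 lists. Against TREM2-KO 1 alone, a comparison chosen after seeing the data and without a test, the TREM2-R47H mean was higher by 0.118 in the APOE cluster and by 0.0397 in disease-associated microglia, and 14 of 23 lists were positive. The off-lineage megakaryocyte and erythroid list, not among the 10, moved too. It had 0.196, 0.0347 and -0.0161 in TREM2-R47H 1 to 3 and 0.110, -0.116 and -0.191 in TREM2-KO 1 to 3.

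No gene passed between TREM2-R47H and TREM2-KO (limma, 0 of 8424), with 770 higher and 401 lower at an unadjusted p below 0.05. Adjusted over the list alone there were 14 calls. Higher in TREM2-R47H were the Alzheimer risk genes ADAM10 (0.216, SE 0.0691), CLU (0.275, SE 0.0813) and FERMT2 (0.275, SE 0.0811), the stress-response factor ATF3 (0.292, SE 0.0755), the replication helicase subunit MCM5 (0.383), CTSD, RUNX1 (0.263), CEBPA (0.225), RAC1 (0.256) and PAX6 (0.362). Lower were MRC1 (-0.250, SE 0.0668) and GFI1 (-0.241, SE 0.0561). The smallest adjusted p over all genes was 0.0707 by limma, for AGPAT4, a phospholipid-synthesis acyltransferase (0.400, SE 0.0692). With at least 10 regions per gene 13 genes passed, among them AGPAT4 (adjusted p = 0.0143 by limma) and BCOR (0.351, adjusted p = 0.0153 by limma), and without replicate 1 there were 34. Genes also passed with the replicate number as a block, AGPAT4 and BCOR among them (adjusted p = 0.0177 for each by limma). The numbers were not taken to pair the libraries. Camera with its preset correlation called Alzheimer risk loci (adjusted p = 0.0182), disease-associated microglia (adjusted p = 0.0120) and antigen presentation (adjusted p = 0.0389), all from limma. With an estimated correlation none held (adjusted p = 0.657, 0.657 and 0.945), and fry called none in a single direction.

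Region by region, TREM2-R47H called 576 regions in 3 of 3 libraries that TREM2-KO called in 0 of 3, and TREM2-KO called 481 that TREM2-R47H did not, against simulated means of 236 and 242. Gained in TREM2-R47H were the gene ends of CRYZ and of PDPN, which encodes podoplanin (1, 13583555 to 13585857), regions inside SYNDIG1 (20, 24608661 to 24610154), the focal adhesion gene TNS3 (7, 47304646 to 47305692), ADAMTS17, ADAMTSL2, ZZZ3 and ASAP1, and 1 region outside gene spans next to APOE. Regions near MEF2C, OLFML3, ABCG1, CXCL8 and RSAD2 were gained too, but not with lists of equal length, where 25 of the 576 gained and 13 of the 481 lost regions were also all-or-none. Lost were the gene ends of PUS7L and PCDHA2 (5, 140794500 to 140795761) and regions inside EEF1E1, STAT4, a transcription factor of cytokine signalling (2, 191127915 to 191128838), ZNF808, PLXNA4 and PDZRN3, and a region near DKK2; those lost near SYK, CCL2 and MRC1 were not all-or-none with lists of equal length.

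SORL1-A528T against SORL1-KO held the most losses. Gene ends called in 3 of 3 SORL1-KO and 0 of 3 SORL1-A528T libraries were those of H2BC3, the protocadherin PCDH7 (4, 30719200 to 30722550), the matrix protein EDIL3 (5, 84381640 to 84385583), NAV2 (11, 19344797 to 19347051), the receptor ROR1 (1, 63773522 to 63775373), KL, the klotho gene (13, 33016466 to 33018065), ZNF763, GLT1D1, MCF2L2 and the actin regulator CORO1C. Near genes of the fixed lists, lost regions lay at MEF2C, MS4A6A, GPNMB, TIMP2, LYVE1, F13A1, IL6, CCL20 and PPARG. Gained were the gene end of CAT and that of the olfactory receptor OR4M1 (14, 19771346 to 19773010) and regions at CEP85L, KCNT2, FBXO33 and GRB10. The totals were 187 gained and 1840 lost, with simulated means of 46.8 and 849. There were 462 and 833 with lists of equal length, of which 11 and 112 were all-or-none in both settings. No gene passed (limma, 0 of 8424; 198 higher and 304 lower at an unadjusted p below 0.05). The smallest adjusted p was 0.0678 by limma for APLN, the apelin gene (0.360, SE 0.0665), and OLFML3 was the 1 call adjusted over the list alone (-0.279, SE 0.0627, lower in 3 of 3 libraries). With the replicate number as a block genes did pass, APLN among them (adjusted p = 0.0409 by limma). Of the lists 19 of 23 were negative and 0 passed (limma; 0 at an unadjusted p below 0.05).

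**Figure D4:**
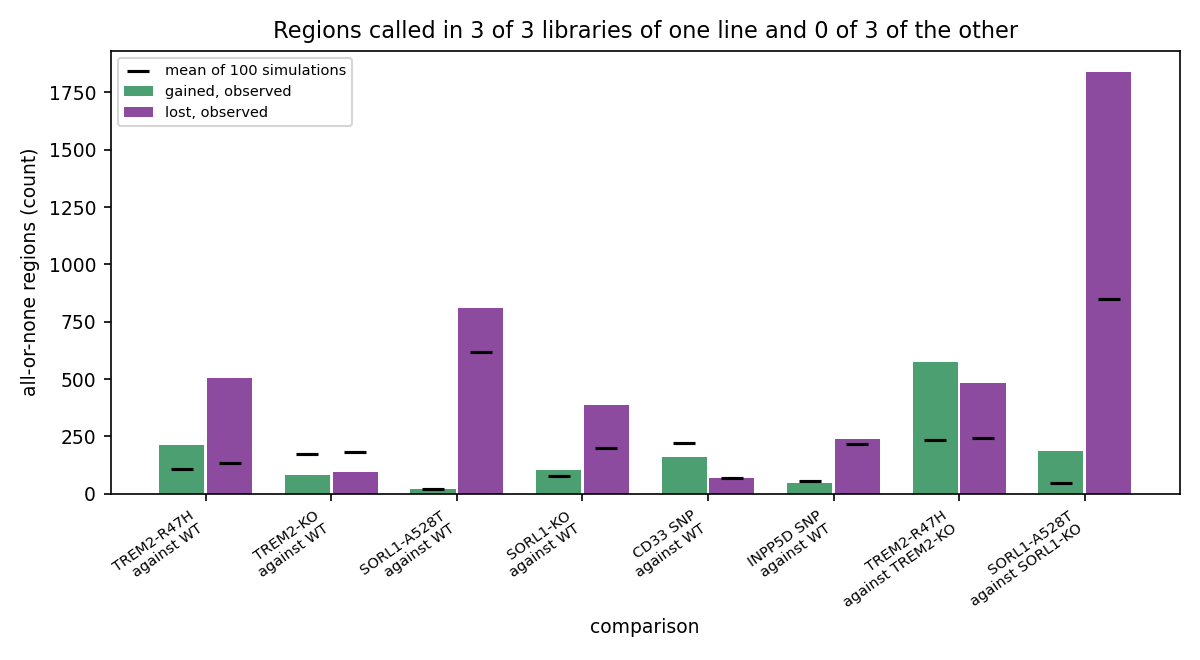
Number of regions (vertical axis) called in 3 of 3 libraries of the first line and 0 of 3 of the second (gained, green) or the reverse (lost, purple) in the 8 comparisons, with black marks for the mean of 100 simulations without a difference between lines. SORL1-A528T against SORL1-KO has the highest bar, 1840 lost regions where the simulated mean is 849.

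Across the 8 comparisons the other splits of the same 6 libraries into 3 and 3 reached higher totals than the real one, up to 6459 regions in TREM2-KO against WT, and in each comparison the highest split kept both shallow replicate 2 libraries together. Among the 4 splits that hold 1 library of each replicate number on each side, the real split had the highest total for TREM2-R47H, SORL1-A528T and SORL1-KO against WT and for both comparisons of alleles of the same gene. It was not the highest for TREM2-KO, CD33 SNP and INPP5D SNP against WT. With only 4 splits a highest rank decides little. In SORL1-A528T the real split also sets the shortest list of each replicate number on the same side.

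Regions lost against WT were shared between edited lines. Regions at KCNJ3, a potassium channel gene (2, 154680907 to 154682079), VEGFC, a lymphatic growth factor gene (4, 176703758 to 176704513), MAST4 (5, 66814363 to 66814865), SH3BGRL2 (6, 79645910 to 79646601) and TRHDE (12, 72141030 to 72141683) were called in 3 of 3 WT libraries and in 0 of 3 in each of the 6 edited lines. Unchanged groups set against the same WT libraries gave 0.74 such regions (at most 3), and 23.3 (at most 33) where 53 were lost in at least 4 lines. These simulations treat libraries of a line as no more alike than others. As many regions particular to 3 libraries as WT has came up in 33 of 100 draws, so the 5 need not mark the edits. The H2BC3 gene end was lost in TREM2-R47H, TREM2-KO, SORL1-A528T and CD33 SNP, and was called in 3 of 3 libraries of WT, SORL1-KO and INPP5D SNP. TREM2-R47H and SORL1-KO shared the most lost regions, 164, where unchanged groups set against the same WT libraries gave 28.1 (at most 43) and independent lists 4.59. TREM2-R47H and SORL1-A528T shared 106 (simulated 45.5, independent 9.58), and TREM2-KO shared 22 with TREM2-R47H (simulated 20.8, independent 1.13) and 29 with SORL1-KO (simulated 29.4, independent 0.87). The simulated counts already hold the shared WT libraries, which the counts for independent lists do not. What lies above the simulated counts could not be tested with separate controls, since 3 WT libraries cannot be split into parts of 2.

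Line-specific regions were most numerous in SORL1-A528T and TREM2-R47H. SORL1-A528T missed 591 regions that at least 15 of the 18 other libraries called, where 7 of 100 draws of 3 libraries gave as many. When each draw held 1 library of each replicate number, 1 of 100 did. That 1 was the line itself, and the highest other draw missed 320. SORL1-A528T has the shortest list of each replicate number, so this rank cannot be told apart from list length. With list lengths equal within each replicate number, a setting chosen after seeing the data, it missed 107 and the highest other draw 73. Among the 591 was the gene end of FSTL1, a follistatin-like gene (3, 120450136 to 120451197). With lists of equal length SORL1-A528T missed 268 and TREM2-R47H 228. TREM2-R47H called 153 regions that at most 3 of the other 18 libraries called, and missed 90 common ones, as many as 18 and 15 of 100 draws gave, and 4 and 4 of 100 with 1 library of each replicate number. WT missed 3 common regions and called 68 rare ones, as many as 69 and 33 of 100 draws gave, and 64 and 24 with 1 library of each number. The gene ends of CRYZ, CAT, PUS7L and ZNF506, each missing from 3 of 3 libraries of 1 line, stood at median percentiles of 95.6, 89.7, 89.5 and 63.8 in the 18 other libraries; singling out gene ends high in the lists was a choice made after their values were seen.

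**Figure D5:**
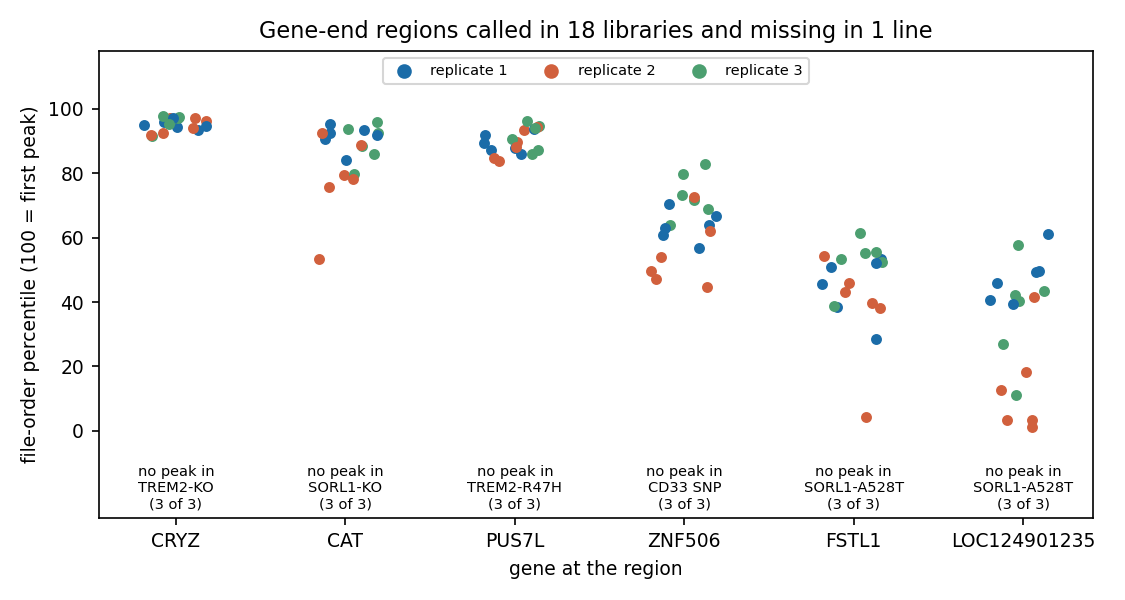
File-order percentile (vertical axis, 100 being the first peak of a list) of the 6 gene-end regions missing from 1 line, in the 18 libraries that called them, with points coloured by replicate number and the line without the peak named under each gene. CRYZ lies at a median of 95.6 and no lower than 91.5, and LOC124901235 at the lowest median, 40.5.

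No chromosome differed as a whole between lines (limma, 0 of 23 in each of the 8 comparisons; 0 at an unadjusted p below 0.05). The smallest unadjusted p was 0.0674 (limma), in TREM2-R47H against TREM2-KO. In that comparison chromosomes did pass with the replicate number as a block, the 1 of the 8 where the block changed the call.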

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

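The tests of gene density and of draws for the X stretch, of list length and, over all 6, of neighbours for the missing gene ends, of draws for the 4 that stayed, of the neighbours of CAT, and of list length, splits and a shared clone for SORL1-A528T were chosen after the result was seen, as were the scan of windows and the percentile that a missing gene end had to reach.

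Peaks on chromosome Y, which entered no comparison, numbered 1297 over the 21 lists.

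In TREM2-R47H the stretch of the X chromosome around BCOR was called more often than in the 18 other libraries, by 0.334. The tables argue against list length and gene density as the whole cause: with lists of equal length the difference was 0.431 (lowest TREM2-R47H library 0.301, highest other 0.151), and with an expectation matched on gene density it was 0.364 (0.238 against 0.088). Of 100 draws of 3 libraries 1 held a window as extreme as the standardized 3.74 seen here. That 1 was TREM2-R47H itself, and the highest other was 3.16. With the density-matched expectation, however, 2 and 6 of 100 draws matched the 2 windows, and 3981 windows were scanned in 7 lines. An extra copy of the segment cannot be told apart from more open chromatin, since 1 region of the stretch was called in all 21 libraries; its percentile was 28.2 higher in TREM2-R47H, with the lowest TREM2-R47H library at 70.1 and the highest other at 75.7. As a hypothesis, chromatin near BCOR may differ in this line, and whether by the variant or by the clone was not tested.

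The gene-end regions of CRYZ, CAT, PUS7L and ZNF506, and of FSTL1 and LOC124901235 in SORL1-A528T, were each missing from 1 line and called in the 18 other libraries. A deletion reaching the neighbours is argued against, as 8 of their 8 neighbouring regions were called in 3 of 3 libraries of the line; CAT had 0 such neighbours, so a deletion there cannot be told apart, and a small deletion at any region was not tested. List length stays open: with lists of equal length 4 of the 6 stayed in all 18 libraries, but FSTL1 stayed in 6 and LOC124901235 in 4, and the 4 cannot be tested alone because staying is what sets them apart. A grouping by chance stays open too: of 100 draws of 3 libraries 8 missed a gene end as high in the lists as the lowest of the 6 (highest other 87.6). With draws held to gene ends that stayed in the 18 libraries, 4 of 100 reached the lowest of the 4 (highest other 85.0), close to the limit, and CRYZ, CAT and PUS7L lay above the highest draw in both counts.

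SORL1-A528T lacked 1840 regions that SORL1-KO called. With lists of equal length 833 were lost, only 112 of them among the 1840, above the 588 of the next comparison but by less than the margin of 1.5 set for it, so list length stays open. The genotype label names TREM2-KO, and with lists of equal length SORL1-A528T had its fewest all-or-none regions against TREM2-KO, 475, as a wrong line name would give, though WT was close at 519 and the highest of the pairs was 1796. Against a shared clone, 3 of 3 SORL1-A528T libraries called the CRYZ gene end that TREM2-KO lacked. Of the 10 splits of the 6 libraries 2 gave as many all-or-none regions as the real 2027 (highest other 3342, which keeps both replicate 2 libraries together; 297 among splits with 1 library of each number on each side), and 10 splits are too few for a share under 0.05.

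For the limma counts the 10 splits per comparison are too few for a share under 0.05. In INPP5D SNP against WT the real split called 1 gene and was the 1 of 10 splits that did (highest other 0). A count of 0 is matched by any split, so the 10 of 10 splits that matched the other counts decide nothing. For the 0 genes of the 7 other comparisons the highest other was 1 in CD33 SNP against WT, 165 in TREM2-R47H against TREM2-KO and 0 in the remaining 5. For the 0 lists and 0 chromosomes of all 8 comparisons the highest other was 10 lists and 13 chromosomes in TREM2-R47H against TREM2-KO and 0 elsewhere. That split set replicates 1 and 3 of TREM2-R47H with replicate 1 of TREM2-KO against the rest, which hold TREM2-KO 2 and 3, and calling so many points to a structure of the samples.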

How the results depend on the processing

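The tests with lists of equal length, the upper part of each list and the expectation matched on gene density were chosen after the result was seen. Over the alternatives run, 313 results kept their direction and side of the threshold or stayed within 1.5 times, 184 moved, 2 reversed, 1 became stronger and 4 weaker. The cause was not tested except where the setting itself explains it. Alternatives by score were not run because the score is constant, and motifs were not run because no genome was used. Depth limits the calls: replicate 2 lists hold at most 67861 peaks, so a region missing there need not be closed.

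With the replicate number as a block, the similarity within lines, taken relative to the mean of the permutations, was 0.0089 (permutation p = 0.00064) where it was -0.0206 without the block. The block called 67 genes, 8 lists and 5 chromosomes in TREM2-R47H against TREM2-KO and 8 genes in SORL1-A528T against SORL1-KO, where the fit without it called 0, and changed no other call. The lowest correlation of same-numbered deviations was 0.07, 0.157 and 0.07 for calls and 0.026, -0.059 and -0.019 for depth-adjusted calls, so at least 1 pair lay under the bound of 0.1 and the numbers were not taken to pair the libraries, although libraries of the same number are alike in depth and, for replicate 2, in a fragment length above the 74 bp of the other numbers; 21 of 21 libraries correlated best with their own number for calls and 9 of 21 for depth-adjusted calls, a hint from the data and not from the design.

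With the replicate block with equal list lengths per replicate number, gained regions were 95 in SORL1-A528T, 68 in SORL1-KO and 33 in CD33 SNP against WT, 259 in TREM2-R47H against TREM2-KO and 350 in SORL1-A528T against SORL1-KO. Lost regions were 236 in SORL1-A528T, 166 in SORL1-KO and 99 in INPP5D SNP against WT and 485 in SORL1-A528T against SORL1-KO. Regions called in a line and rarely elsewhere were 70 in TREM2-R47H, 40 in TREM2-KO, 81 in SORL1-A528T, 18 in SORL1-KO, 8 in CD33 SNP, 10 in INPP5D SNP and 29 in WT. Regions missed and common elsewhere were 107 in SORL1-A528T, 4 in SORL1-KO, 3 in CD33 SNP, 2 in INPP5D SNP and 0 in WT.

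With equal list lengths over all libraries (depth matching by file order), gained regions were 441 in TREM2-R47H, 129 in SORL1-A528T, 232 in SORL1-KO and 114 in INPP5D SNP against WT and 462 in SORL1-A528T against SORL1-KO. Lost regions were 390 in SORL1-A528T, 109 in INPP5D SNP and 833 in SORL1-A528T against SORL1-KO. Regions called and rare elsewhere were 86 in SORL1-A528T, 75 in SORL1-KO, 30 in CD33 SNP and 17 in WT. Regions missed were 228 in TREM2-R47H, 36 in TREM2-KO, 268 in SORL1-A528T, 36 in SORL1-KO, 4 in CD33 SNP and 6 in WT. Genes past the threshold were 1 in TREM2-R47H and 0 in INPP5D SNP against WT, 2 in TREM2-R47H against TREM2-KO and 3 in SORL1-A528T against SORL1-KO.

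With the upper part of each list, where fewer peaks lower counts by construction, gained regions were 71 in TREM2-R47H, 11 in TREM2-KO, 3 in SORL1-A528T, 32 in SORL1-KO, 43 in CD33 SNP and 4 in INPP5D SNP against WT, 205 in TREM2-R47H against TREM2-KO and 98 in SORL1-A528T against SORL1-KO. Lost regions in the same order were 299, 25, 428, 194, 7, 60, 239 and 1026. Regions called and rare elsewhere were 69 in TREM2-R47H, 19 in TREM2-KO, 5 in SORL1-A528T, 21 in SORL1-KO, 47 in CD33 SNP, 1 in INPP5D SNP and 19 in WT. Regions missed were 4 in TREM2-KO, 392 in SORL1-A528T, 1 in INPP5D SNP and 0 in WT. Genes were 1 in TREM2-KO and 0 in INPP5D SNP against WT, 7 in TREM2-R47H against TREM2-KO and 2 in SORL1-A528T against SORL1-KO.

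With peaks covering at least 50% of a region, 34 regions were gained in SORL1-A528T against WT, 19 were missed in TREM2-KO and 5 in WT, and 0 genes passed in INPP5D SNP. With at least 10 regions per gene, 0 genes passed in INPP5D SNP, where NAA35 has too few regions to enter, 13 in TREM2-R47H against TREM2-KO and 3 in SORL1-A528T against SORL1-KO. With the expectation matched on gene density, 6 genes and 2 lists passed in TREM2-R47H against TREM2-KO, and camera with a preset correlation called 3 lists there.

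Leaving out each replicate number in turn raised the counts by construction, since 2 libraries per line decide each region. The similarity relative to the permutations ranged from -0.0628 to 0.0018 and the F ratio of peak number from 0.214 to 1.27. Against WT, gained regions ranged from 710 to 2636 in TREM2-R47H, 468 to 3428 in TREM2-KO, 198 to 474 in SORL1-A528T, 627 to 1216 in SORL1-KO, 939 to 2121 in CD33 SNP and 321 to 779 in INPP5D SNP. Lost regions ranged from 1065 to 4301, 271 to 3197, 1853 to 9173, 1186 to 4848, 299 to 1668 and 709 to 3766 in that order. TREM2-R47H against TREM2-KO had 1228 to 4789 gained and 1404 to 5185 lost, and SORL1-A528T against SORL1-KO 558 to 1342 and 4004 to 6262. Regions called and rare elsewhere were 552 to 1731 in TREM2-R47H, 324 to 2834 in TREM2-KO, 119 to 249 in SORL1-A528T, 376 to 454 in SORL1-KO, 619 to 1422 in CD33 SNP, 182 to 316 in INPP5D SNP and 209 to 1437 in WT. Regions missed were 165 to 512, 23 to 524, 1169 to 3440, 76 to 404, 5 to 36, 53 to 314 and 10 to 67 in that order. Genes ranged from 0 to 2 in SORL1-KO against WT and 0 to 34 in TREM2-R47H against TREM2-KO, with the highest value in both without replicate 1, lists from 0 to 5 in the latter, and other counts of genes, lists and chromosomes were 0. NAA35 ranged from -0.457 to -0.387 in INPP5D SNP against WT and passed in none of the 3.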

Other observations

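The values of this part were chosen after they were seen. NAA35 had a negative difference from WT in all 6 edited lines, from -0.177 in CD33 SNP to -0.412 in INPP5D SNP, and passed in INPP5D SNP alone. FCER1A, a mast cell receptor gene, was negative in all 6 as well, from -0.196 to -0.423, around a WT mean of 0.262 ± 0.316 (SD, n = 3), and NLRP3 was positive in all 6, from 0.0493 to 0.204. The 6 differences share the same 3 WT libraries and were not tested jointly. Regions inside HFM1 (1, 91403971 to 91405058) and KTN1 (14, 55582634 to 55583386) were called in 3 of 3 libraries of 4 edited lines and 0 of 3 WT libraries.

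Technical explanations were tried for 4 patterns, of which 3 are given. The other was the set of 10 lists higher in TREM2-R47H than in TREM2-KO. Its criterion was moved from the adjusted to the unadjusted p once 0 lists had passed, and it was set aside after its values were seen: 6 lists kept an unadjusted p below 0.05 with the expectation matched on gene density, between the bounds stated for it, and the mast cell (0.0643) and mesenchyme (0.0480) lists, which are not microglial, were among the 10. The pattern of missing gene ends, found among the named regions, took its place.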
